A study of Mus musculus with 8 samples.

How the data were processed

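RNA was measured on 8 one-colour Cy3 Agilent arrays, 1 per sample, in secondary neurospheres from the hippocampus of adult mice. The labels give 4 groups of 2 arrays: WT and Sirt1 KO cells of a mixed strain background cultured for 6 days, and C57BL/6 wild-type cells cultured for 5 days and then given DMSO or resveratrol for 24 hours. In the WT and Sirt1 KO groups replicate 1 came from females and replicate 2 from males, and all DMSO and resveratrol arrays came from males, per the labels.

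Signals were read with Agilent Feature Extraction, version 10.7 per the submitters' processing notes and 10.7.3.1 per the file headers. The deposited scanner files hold an intensity for each spot, which the scanner software had corrected for background and for spatial trends within the array, with no normalization between arrays. The deposited value table holds log2 values, and the authors had quantile normalized them, apparently in separate sets: the ordered values of the 6 arrays of slides 1 and 2 matched within a log2 difference of 0.01 for at least 99.6% of probes, those of the 2 arrays of slide 3 likewise, and the sets differed in median (6.28 and 6.01). The software of that step is not stated. That table served as an alternative. The headers name an older genome build than the reference annotation used here, so no coordinates are given.

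Each array held 45018 spots, of which 1639 were controls. Replicate spots of a probe were averaged, which left 41174 probes. The log2 of the processed intensity was centred on the 75th percentile of its array. Probes were kept where the scanner software called them well above background on both arrays of at least 1 group (26361 probes). Symbols came from matching the accessions in the files to a RefSeq table, and 14256 probes without a match were left out of all gene counts. The kept probe with the highest mean stood for its gene, which gave 13306 genes; 4977 of them had several kept probes.

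Groups were compared with limma 3.58.1 in R 4.3.3, with a fit of 4 group means over all 8 arrays, moderated variances with an intensity trend, two-sided tests and Benjamini-Hochberg adjustment over the 13306 genes within each comparison, at an adjusted p of 0.05. The comparisons were Sirt1 KO minus WT, resveratrol minus DMSO, and the difference between these differences. The arrays lay on 3 slides scanned on 2 days, per the file headers. Slide 1 held WT 1, DMSO 1 and resveratrol 1, slide 2 held Sirt1 KO 1, DMSO 2 and resveratrol 2, and slide 3, the only slide of its scan day, held WT 2 and Sirt1 KO 2. The replicate number is thus the slide in the treatment groups, and in the genotype groups it is sex, with WT 1 and Sirt1 KO 1 on different slides. A check of pairing correlated the deviations from the group mean across genes between arrays of the same replicate number: 0.736 for WT with Sirt1 KO, 0.834 for DMSO with resveratrol, 0.596 for WT with DMSO and 0.643 for Sirt1 KO with resveratrol. Replicate number within each arm as a block, and slide as a block, were therefore each fitted beside the fit of group means. The slide block is shared by the arms, and its slide 2 term rests largely on the replicate differences of DMSO and resveratrol. In Sirt1 KO 1 minus WT 1 it thus removes replicate differences of another strain, and not slide alone. With it the median Sirt1 KO minus WT difference over all genes moved from -0.0317 to -0.109. The labels do not say whether replicates are separate cultures or animals beyond the difference in sex, so p-values measure only the spread between these samples.

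The 32 gene lists, fixed before the data were examined, covered the Notch pathway, neural stem cell, neuronal lineage, astrocyte, oligodendrocyte precursor, mature oligodendrocyte, microglia and macrophage, endothelial, pericyte with smooth muscle and fibroblast, ependyma with choroid plexus, blood, mitosis, DNA replication, p53 targets, sirtuins and NAD metabolism, PGC-1alpha and mitochondrial genes, FoxO targets, NF-kB and inflammatory genes, interferon response, aryl hydrocarbon receptor targets, NRF2 antioxidant genes, cholesterol synthesis, lipogenesis, integrated stress response, unfolded protein response, hypoxia and glycolysis, immediate early genes, Hedgehog and Wnt targets, BMP and TGF-beta targets, extracellular matrix, sex-linked genes and the chromosome 10 neighbours of Sirt1. Each had at least 5 measured members. They were tested with camera from limma with a preset correlation between genes of 0.01, which sets a list against all other genes, again with an estimated correlation, and with fry, whose p-value asks whether the genes of a list move on balance in 1 direction without comparing them with other genes. Adjustment was over the 32 lists within each comparison, and members were also counted as past the test when adjusted over the list alone. All other list tests below, including those with a block, used camera with the preset correlation.

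Named genes followed a rule fixed before the data were examined. For Sirt1 KO against WT and for resveratrol against DMSO it takes Sirt1 and, among genes past the adjusted threshold whose differences between single arrays of the groups all share a sign, the 12 largest rises and 12 largest falls. Where fewer pass, it fills up with the smallest unadjusted p among genes that differ by at least 1 on the log2 scale in that direction. Clone and predicted names are left out. For lists it takes the 2 to 4 members with the smallest unadjusted p, and for the difference between the effects the 5 largest in each direction that pass. As no gene passed in the fit of group means, genes are described by values, and for the difference between the effects the genes past the test with the replicate block were used, a choice made after the counts were seen. Where both arrays of a group were not well above background at a gene's probe, the difference is given as a lower bound: the mean of the brighter group over the mean of the dim arrays, each dim array set to the lowest signal called well above background on it if its own was lower. The bound holds for the background-subtracted signals used here, and normexp can give a smaller difference. Some genes that the rule takes are not used here. Genes named outside the rule are marked as chosen after their values were seen.

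The tests were tried on simulated data, with 200 changed genes among 13306 and 20 simulations per comparison. The noise was normal, with the residual spread of each gene and no correlation between genes or between arrays. Without a block, the shift that arrays of the same replicate number share thus entered as separate noise for each array. The rates for the fit of group means therefore need not hold for the real arrays. The fit of group means recovered 1.42% of genes changed by 1 on the log2 scale, 32.0% at 2 and 59.0% at 3 for Sirt1 KO against WT, and 1.12%, 31.6% and 55.8% for resveratrol against DMSO. With replicate number as a block it recovered 39.9%, 75.7% and 88.9%, and 40.4%, 76.1% and 88.3%. Unchanged genes called per simulation numbered 2.7 to 3.35. A planted list of 30 genes shifted by 0.5 was found in 20 of 20 simulations under each fit, and a random list of that size in at most 1 of 20. A list counted as found at an unadjusted camera p under 0.05, without the adjustment over 32 lists. Real list genes can be correlated (estimate 0.825 for DNA replication) and the simulated ones were not. The simulation thus does not show how often the list calls below are false.

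Alternatives were quantile normalization, the authors' deposited values, no filter on dim probes, only probes well above background on all 8 arrays, the mean of a gene's probes, no intensity trend, only the 4 arrays of a comparison, sex as a covariate, both blocks, other thresholds, and leaving out each of the 8 arrays in turn. A planned background correction on mean signals was not run, because the files used here hold median and not mean raw signals. In its place normexp with an offset of 50 was run on median signals, chosen after seeing the data, as were normexp with 1 median background per array, the replicate block with quantile normalization, and the crossed split that sets replicate 1 of the control and replicate 2 of the case against the other arrays of an arm. Probes without a symbol, control spots and the probe positions were not analysed here.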

Results

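Gene expression was profiled in secondary neurospheres, free-floating clusters that neural stem and progenitor cells form after primary neurospheres are dissociated and seeded again. The series title sets loss of SIRT1 function beside gain of function. SIRT1 is an NAD-dependent protein deacetylase, and resveratrol is a plant polyphenol used to activate it. There were 2 arrays each for WT, Sirt1 KO, DMSO and resveratrol, 8 in all. The dose of resveratrol is 10 in the label, with its unit written as "mm". The share of the 41174 probes well above background ran from 53.1% (WT 2) to 72.0% (DMSO 1), and the 75th percentile of the signal from 257 (WT 2) to 910 (Sirt1 KO 1), with 0 saturated spots. With 2 arrays per group, the number of arrays limits the precision of every value. The first principal component, 49.1% of the variance, separated replicate 1 from replicate 2 in all 4 groups, and the second, 26.1%, separated the genotype arm from the treatment arm. The 75th percentile was 257 to 388 on the replicate 2 arrays and 740 to 910 on the replicate 1 arrays. Replicate number thus also goes with signal strength. Y-linked Ddx3y read -7.87 and -7.94 on the arrays labelled female and between -0.41 and 0.97 on the 6 arrays labelled male, on the log2 scale relative to the 75th percentile of each array.

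Sirt1 KO was compared with WT to ask which genes differ when SIRT1 is lost. Genes of mitosis and DNA replication were lower in the Sirt1 KO arrays, and genes of astrocytes and of glycolysis were higher, under a preset correlation between genes. With an estimated correlation none of these lists passed (adjusted p = 0.209 for mitosis, 0.533 for DNA replication, 0.209 for astrocyte and 0.442 for hypoxia and glycolysis genes). The glycolysis list turned to lower without Sirt1 KO replicate 1 (adjusted p = 0.846), and the DNA replication call was lost without that array (adjusted p = 0.448) or WT replicate 2 (adjusted p = 0.0517). Without an array the fit sets arrays of different replicate numbers against each other, and these differed for the glycolysis list in every group. Within pair 2, which lacks Sirt1 KO replicate 1, the glycolysis list was higher by a median of 0.24. Among single genes, Hes5, a Notch target that keeps neural progenitors undifferentiated, was 3.16-fold higher (log2 difference 1.66, SE 0.35, n = 2 arrays per group), by 1.64 in pair 1 and 1.68 in pair 2. Apoe, the lipid carrier that astrocytes secrete, was 2.72-fold higher (1.45, SE 0.40), by 1.37 and 1.52 in the pairs, and Dera, an aldolase of deoxyribose breakdown, was 3.71-fold lower (-1.89, SE 0.41).

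The astrocyte list rose relative to all other genes, with a median of 0.49 over 19 measured members, and 12 members were higher in both pairs (camera, adjusted p = 1.28e-07; adjusted p = 0.209 with an estimated correlation). Gfap, the intermediate filament of astrocytes and adult neural stem cells, was not well above background in WT and at least 1.60-fold higher in Sirt1 KO. Under normexp on median signals Gfap turned to lower (-1.18), and with 1 background per array it was higher by less than this bound. The water channel Aqp4 differed by 2.25 (SE 0.63) and the glycolytic enzyme Aldoc by 0.95 (SE 0.41). The neural stem cell list rose as well (median 0.10 over 20 members, adjusted p = 0.000626; adjusted p = 0.209 with an estimated correlation), with 9 members higher and 5 lower in both pairs and with pair medians of 0.30 and -0.07. Its leading members were Hes5, Gfap, the transcriptional inhibitor Id4 (1.05) and the homeodomain protein Hopx (0.69). Mature oligodendrocyte genes rose with a median of 0.51 over 14 members, 8 of them higher in both pairs, with pair medians of 0.76 and 0.07 (adjusted p = 0.000514; adjusted p = 0.209 with an estimated correlation). Examples are the myelin genes Cnp (0.54) and Mal (0.84), the sulfotransferase Gal3st1 (0.52) and the fatty acid hydroxylase Fa2h (1.52). The Notch pathway list rose with a median of 0.14 over 24 members, 11 of them higher in both pairs (adjusted p = 0.00345; adjusted p = 0.442 with an estimated correlation). Beside Hes5 its leading members were Mfng, which modifies Notch receptors with sugars (1.59, SE 0.39), the target Hey1 (0.70) and the receptor Notch3 (0.75). Without Sirt1 KO replicate 1 the adjusted p = 0.233 for neural stem cell, 0.714 for mature oligodendrocyte and 0.578 for Notch genes. Without WT replicate 1 it was 0.0713 for neural stem cell and 0.0705 for mature oligodendrocyte genes, and without WT replicate 2 it was 0.222 for Notch genes. Normexp on median signals turned the mature oligodendrocyte list to lower (adjusted p = 0.603) and ended the Notch (0.0701) and neural stem cell calls (0.0698). With 1 background per array these calls stayed (adjusted p = 0.000717, 0.000717 and 0.00703). In all genes together, 23.4% were higher and 32.6% lower in both pairs.

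Hypoxia and glycolysis genes rose with a median of 0.50 over 30 members, 24 of them higher in both pairs (adjusted p = 2.65e-07; adjusted p = 0.442 with an estimated correlation). Aldoc (0.95), enolase Eno1 (0.66), triose phosphate isomerase Tpi1 (0.75) and Pfkfb4 (0.32), which sets the level of a glycolytic activator, led the list. The rise was 0.84 in pair 1 and 0.24 in pair 2. The hypoxia and glycolysis list turned to lower without Sirt1 KO replicate 1 (adjusted p = 0.846), and without WT replicate 2 its adjusted p = 0.222. FoxO targets rose with a median of 0.18 over 20 members, 10 of them higher in both pairs (adjusted p = 0.0145; adjusted p = 0.442 with an estimated correlation). They were led by Txnip, an inhibitor of thioredoxin (1.73), and the stress gene Gadd45a (0.89), with pair medians of 0.41 and -0.01. Lipogenesis genes rose with a median of 0.10 over 21 members, led by the cholesterol exporter Abca1 (0.85) and malic enzyme Me1 (0.95), and 9 were higher in both pairs (adjusted p = 0.024; adjusted p = 0.264 with an estimated correlation). NRF2 antioxidant genes rose with a median of 0.07 over 25 members, 10 of them higher and 7 lower in both pairs (adjusted p = 0.0417; adjusted p = 0.546 with an estimated correlation). With slide as a block the FoxO, lipogenesis and NRF2 lists were no longer past the test (adjusted p = 0.197, 0.0512 and 0.472), and the replicate block ended the NRF2 call (adjusted p = 0.0628). The slide block rests largely on replicate differences of the treatment arm, so losses under it do not reflect slide alone. The NRF2 call also ended with quantile normalization (adjusted p = 0.0567), the mean of a gene's probes (0.0974) and no intensity trend (0.0506), and the lipogenesis call with the mean of a gene's probes (0.0796). Without Sirt1 KO replicate 1 FoxO targets turned to lower (adjusted p = 0.915), and without WT replicate 1 their adjusted p = 0.445. Lipogenesis had an adjusted p = 0.0713, 0.337, 0.291 and 0.105 without WT 1, Sirt1 KO 1, WT 2 and Sirt1 KO 2, and NRF2 antioxidant genes had 0.131, 0.142, 0.222 and 0.384. The NRF2 list also had an adjusted p = 0.0533 without resveratrol replicate 1 and 0.0593 without resveratrol replicate 2.

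The mitosis list fell with a median of -0.43 over 29 measured members, and 25 members were lower and 0 higher in both pairs (camera, adjusted p = 7.14e-12; adjusted p = 0.209 with an estimated correlation). The spindle protein Nusap1 (-0.52), the transcription factor Foxm1 (-0.55), cyclin Ccna2 (-0.57) and the kinetochore protein Nuf2 (-0.48) led it. DNA replication genes fell with a median of -0.41 over 31 members, 22 of them lower and 0 higher in both pairs (adjusted p = 2.92e-07; adjusted p = 0.533 with an estimated correlation). The nucleotide supply enzyme Tk1 differed by -0.54, and Gins3 and Cdc45, parts of the replicative helicase, by -0.59 and -0.61. The blood list of 5 members fell with a median of -0.45 (adjusted p = 0.0417; adjusted p = 0.533 with an estimated correlation), with Slc4a1 at -0.77 and Cd79a at -0.49, and it was not past the test with replicate number as a block (adjusted p = 0.124) or slide as a block (adjusted p = 0.219), with quantile normalization (0.0635) or without the filter on dim probes (0.312). The DNA replication list had an adjusted p = 0.448 without Sirt1 KO replicate 1 and without WT replicate 2 an adjusted p = 0.0517. For the blood list it was 0.915 without Sirt1 KO 1, 0.471 without WT 2, 0.0713 without WT 1, 0.0564 without DMSO 1, 0.152 without DMSO 2 and 0.0528 without resveratrol 2. Mitosis and astrocyte lists stayed past the test, with the preset correlation, when each of the 8 arrays was left out in turn. The DMSO and resveratrol arrays enter this comparison mainly through the spread, so leaving them out tests little. Normexp on median signals ended the mitosis call (adjusted p = 0.354) and the DNA replication call (adjusted p = 0.854), while normexp with 1 background per array kept them (adjusted p = 2.64e-16 and 6.57e-10).

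**Figure D1:**
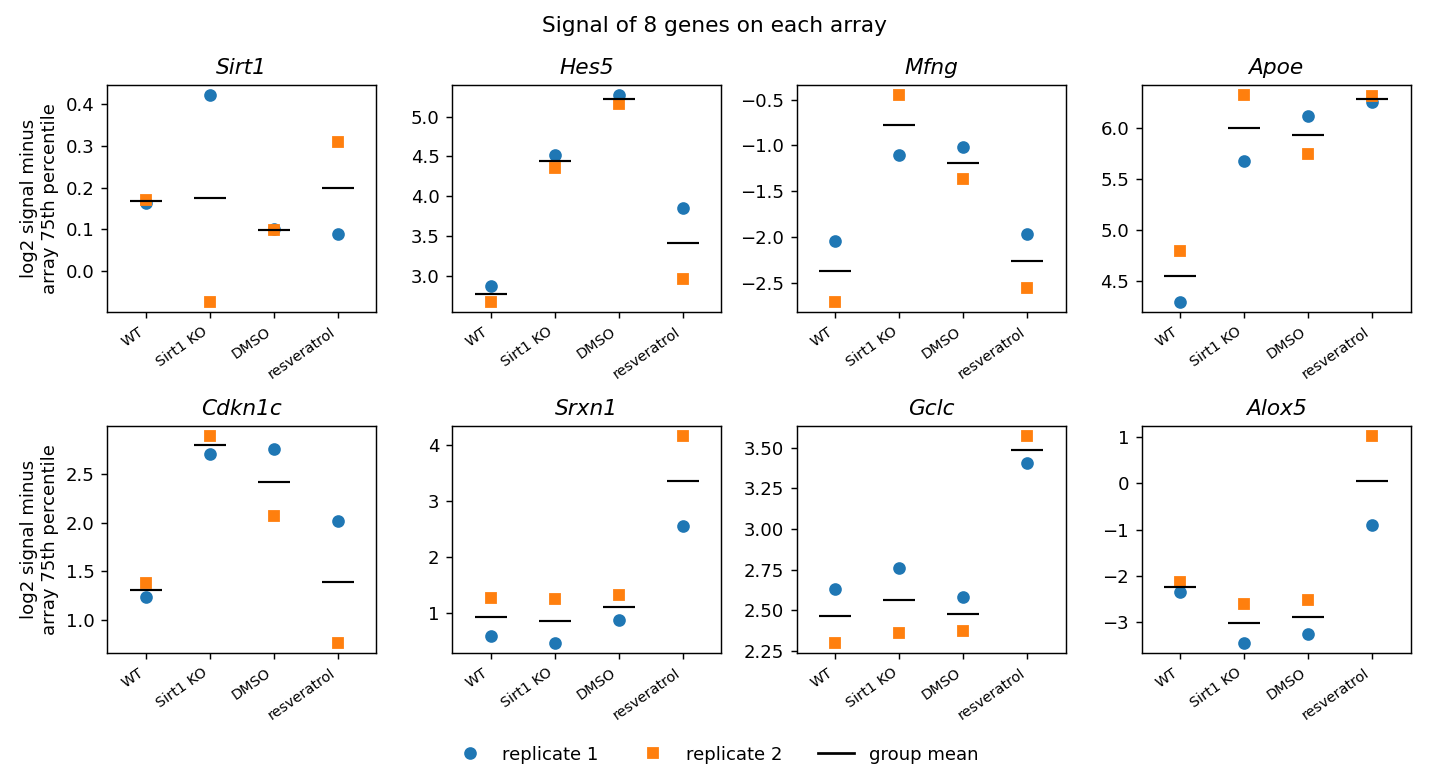
Signal of 8 genes on each array, as log2 signal minus the 75th percentile of the array (vertical axis), for WT, Sirt1 KO, DMSO and resveratrol (horizontal axis); circles are replicate 1, squares replicate 2 and bars the mean of 2 arrays. Hes5 averaged 2.78 in WT, 4.44 in Sirt1 KO, 5.22 in DMSO and 3.41 in resveratrol, while both Sirt1 KO arrays lay on either side of the WT arrays for Sirt1.

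Further genes higher in Sirt1 KO were the arginine deiminase Padi2 (1.78, SE 0.31), the zinc finger factor Sp8 (2.14, SE 0.41), the basic helix-loop-helix factor Scx (1.61, SE 0.35), Serinc2 (1.70, SE 0.39), the lipoprotein lipase inhibitor Angptl4 (1.42, SE 0.37), the potassium channel Kcnn2 (1.38, SE 0.36), the protease inhibitor Serpinb1a (1.35, SE 0.36) and the retinol dehydrogenase Rdh5 (1.30, SE 0.30). Helt, a repressor of the Hes family, was not well above background in WT and at least 2.64-fold higher in Sirt1 KO. Lower in Sirt1 KO were the integrin Itga8 (-1.68, SE 0.33), the lipoxygenase Alox12 (-2.24, SE 0.51), the G protein subunit Gng3 (-1.40, SE 0.49), the homeobox gene Lhx4 (-1.37, SE 0.47), the exchange factor Rapgef5 (-1.16, SE 0.31), the TGF-beta co-receptor Eng (-1.16, SE 0.34), the Wnt regulator Nkd2 (-1.12, SE 0.41) and Lrrc46 (-1.10, SE 0.32). Under normexp on median signals Sp8 (-0.45), Helt (-0.70), Gfap (-1.18) and Angptl4 (-0.24) turned to lower, and with 1 background per array they were higher (0.66, 0.62, 0.36 and 0.75), for Helt and Gfap by less than the bounds given. Laminin Lamc3 and Ptchd4 were not well above background in Sirt1 KO and at least 1.15-fold and 1.37-fold lower there. With 1 background per array Ptchd4 (-0.27) differed by less than its bound. With replicate number as a block, Hes5 (adjusted p = 0.0106), Scx (0.0267), Serpinb1a (0.0214), Padi2 (0.0392), Sp8, Serinc2 and Angptl4 (0.0411 each) and Kcnn2 (0.0456) rose, and Dera (0.00885) and Gng3 (0.0375) fell.

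limma called 0 of 13306 genes between Sirt1 KO and WT in either direction (158 at an unadjusted p under 0.05, where chance gives 665; smallest adjusted p = 1). The replicate block gave 41 rises and 9 falls (1787 at an unadjusted p under 0.05), and 24 genes in all with quantile normalization. With slide as a block the count was 0 (1237 at an unadjusted p under 0.05; smallest adjusted p = 0.294). Leaving out Sirt1 KO replicate 1 gave 5 genes and leaving out Sirt1 KO replicate 2 gave 3, all lower. A difference of at least 2-fold upward was found in both pairs for 75 genes and downward for 22, and 29 genes differed by 2-fold in opposite directions. Differences correlated at 0.176 across genes between pair 1, which spans slides 1 and 2, and pair 2, which lies within slide 3.

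Sirt1 mRNA itself differed by 0.0061 between the genotypes (SE 0.24, adjusted p = 1), with 0.26 in pair 1 and -0.24 in pair 2. Its second probe differed by -0.30 (0.33 in pair 1 and -0.93 in pair 2), and both probes were well above background on all 8 arrays. Where the probes lie relative to the deleted part of the gene is not known here, so these values do not test the genotype.

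Across the 32 lists, 8 rose and 3 fell in Sirt1 KO, and 0 were past the test with an estimated correlation (smallest adjusted p = 0.209) or with fry. With replicate number as a block 10 lists passed, 9 of them shared, and with slide as a block 8 passed, 7 of them shared. Over all genes, the block called 3 astrocyte, 3 hypoxia and glycolysis, 2 neural stem cell, 1 Notch and 0 mitosis or DNA replication genes in the direction of their list. Adjusted over the list alone, it called 10 astrocyte genes, 18 hypoxia and glycolysis genes, 7 neural stem cell genes with 2 more lower, 5 Notch genes, 24 mitosis genes and 22 DNA replication genes. The corresponding counts over all genes and adjusted over the list alone were 1 and 3 for mature oligodendrocyte genes, 0 and 3 for FoxO targets, 1 and 2 for lipogenesis, 1 and 2 for NRF2 antioxidant genes and 0 and 0 for blood. Without a block the list alone gave 1 gene, Hes5 in the neural stem cell list. A crossed split, which sets WT 1 and Sirt1 KO 2 against WT 2 and Sirt1 KO 1, passed 3 lists: DNA replication, FoxO targets, and hypoxia and glycolysis (smallest adjusted p = 0.00191).

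Lists not past the test in Sirt1 KO against WT included the other cell types: neuronal lineage (adjusted p = 0.331), oligodendrocyte precursor (0.308), microglia and macrophage (0.331), endothelial (0.187), pericyte with smooth muscle and fibroblast (0.394), and ependyma with choroid plexus (0.687). Sirtuins and NAD metabolism (0.394), PGC-1alpha and mitochondrial genes (0.155), p53 targets (0.133), NF-kB (0.0773), interferon response (0.177), aryl hydrocarbon receptor targets (0.394) and cholesterol synthesis (0.155) did not pass either. The same holds for the integrated stress response (0.892), unfolded protein response (0.4), immediate early genes (0.308), Hedgehog and Wnt targets (0.152), BMP and TGF-beta targets (0.152), sex-linked genes (0.687) and the chromosome 10 neighbours of Sirt1 (0.601). The extracellular matrix list (adjusted p = 0.137) passed with replicate number as a block (adjusted p = 0.0123) and with slide as a block (adjusted p = 0.000393). Both blocks used the preset correlation, and without a block the estimated correlation gave an adjusted p = 0.533. In 5 of these lists, which are sirtuins, PGC-1alpha, BMP and TGF-beta, integrated stress response and unfolded protein response, the median, the mean and the test differed in sign.

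Resveratrol was compared with DMSO, its solvent, to ask how 24 hours of the compound changed wild-type neurospheres. Antioxidant genes driven by NRF2, p53 targets and interferon response genes were higher after resveratrol, and oligodendrocyte precursor and Notch genes were lower, under a preset correlation between genes. With an estimated correlation none of these lists passed (adjusted p = 0.131 for NRF2, 0.346 for p53, 0.131 for interferon, 0.131 for oligodendrocyte precursor and 0.261 for Notch genes). The oligodendrocyte precursor and Notch calls were also lost without resveratrol replicate 2 (adjusted p = 0.0673 and 0.406). Srxn1, which repairs oxidized peroxiredoxins, was 4.77-fold higher (log2 difference 2.25, SE 0.56, n = 2 arrays per group), by 1.67 in pair 1 and 2.83 in pair 2. Alox5, the enzyme that starts leukotriene synthesis, was 7.68-fold higher (2.94, SE 0.65), and Hes5 was 3.50-fold lower (-1.81, SE 0.35), by -1.41 and -2.20 in the pairs.

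The NRF2 antioxidant list rose with a median of 0.86, and all 25 of its 25 members were higher in both pairs (camera, adjusted p = 2.29e-20; adjusted p = 0.131 with an estimated correlation). Gclc, the catalytic subunit for glutathione synthesis, differed by 1.01 (SE 0.26), the ferritin light chain Ftl1 by 0.96 (SE 0.28) and the glutathione transferase Gsta4 by 1.26 (SE 0.46). Targets of p53 rose with a median of 0.51 over 27 members, 24 of them higher in both pairs (adjusted p = 2.37e-10; adjusted p = 0.346 with an estimated correlation). The death receptors Fas (1.36, SE 0.35) and Tnfrsf10b (1.31, SE 0.41), Trp53inp1 (0.73) and the desmosome protein Perp (2.28, SE 0.80) led them. Interferon response genes rose with a median of 0.64 over 20 members, 17 of them higher in both pairs (adjusted p = 2.05e-08; adjusted p = 0.131 with an estimated correlation). Among them were the antiviral genes Rsad2 (1.18, SE 0.34) and Bst2 (0.87) and the immunoproteasome subunits Psmb9 (1.04) and Psmb8 (0.89). These 3 lists stayed past the test, with the preset correlation, when each of the 8 arrays was left out in turn. The WT and Sirt1 KO arrays enter this comparison mainly through the spread, so leaving them out tests little. In all genes together, 35.4% were higher and 33.0% lower in both pairs.

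Extracellular matrix genes rose with a median of 0.31 over 26 members, 16 of them higher in both pairs, led by the collagen Col18a1 (2.21, SE 0.48), the protease Adamts1 (0.66) and the gelatinase Mmp2 (1.16) (adjusted p = 0.000569; adjusted p = 0.261 with an estimated correlation). The 5 measured aryl hydrocarbon receptor targets rose with a median of 0.51, with Cyp1b1, which oxidizes polycyclic compounds, at 0.57 and the quinone reductase Nqo1 at 1.22 (adjusted p = 0.00409; adjusted p = 0.261 with an estimated correlation). Nqo1 is also on the NRF2 antioxidant list, so these lists are not separate. NF-kB and inflammatory genes rose with a median of 0.25 over 13 members, with the chemokine Cxcl10 at 1.53 and Nfkb2 at 0.65 (adjusted p = 0.0138; adjusted p = 0.394 with an estimated correlation). Immediate early genes rose with a median of 0.26 over 25 members, with Klf4 at 0.62, Fosl1 at 1.41 and Fos at 0.69 (adjusted p = 0.0142; adjusted p = 0.441 with an estimated correlation). Without DMSO replicate 2 the adjusted p = 0.71 for extracellular matrix, 0.124 for aryl hydrocarbon receptor targets and 0.112 for NF-kB, and without resveratrol replicate 1 it was 0.652, 0.127 and 0.0858. The NF-kB list also had an adjusted p = 0.276 without resveratrol replicate 2, and the immediate early genes had an adjusted p = 0.684 without DMSO replicate 1 and 0.488 without resveratrol replicate 2. Normexp on median signals and normexp with 1 background per array ended the calls of NF-kB (adjusted p = 0.184 and 0.208) and immediate early genes (0.06 and 0.0591), and so did, for NF-kB, keeping only probes well above background on all arrays (0.212).

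Oligodendrocyte precursor genes fell with a median of -0.23 over 15 members, 13 of them lower in both pairs (adjusted p = 1.87e-06; adjusted p = 0.131 with an estimated correlation). The growth factor receptor Pdgfra (-1.15, SE 0.49), the transcription factor Sox8 (-0.58), C1ql1 (-0.64) and Lhfpl3 (-0.45) led them. Mature oligodendrocyte genes fell with a median of -0.29 over 14 members, 8 of them lower in both pairs, with Gal3st1 at -0.97 and Cnp at -0.42 (adjusted p = 0.0181; adjusted p = 0.261 with an estimated correlation). The Notch pathway list fell with a median of -0.13 over 24 members, 13 of them lower in both pairs, led by Hes5, the ligand Dll3 (-0.78), the feedback inhibitor Nrarp (-0.89) and Mfng (-1.07) (adjusted p = 7.74e-05; adjusted p = 0.261 with an estimated correlation). Hedgehog and Wnt targets fell with a median of -0.27 over 16 members, with Rnf43 at -0.54 and Hhip at -0.65, both feedback inhibitors (adjusted p = 0.0181; adjusted p = 0.261 with an estimated correlation). Without resveratrol replicate 2 the adjusted p = 0.0673 for oligodendrocyte precursor, 0.615 for mature oligodendrocyte and 0.406 for Notch genes, and the Hedgehog and Wnt list turned to higher (adjusted p = 0.615). Without DMSO replicate 1 it was 0.235 for mature oligodendrocyte, 0.482 for Notch and 0.56 for Hedgehog and Wnt genes, and without DMSO replicate 2 it was 0.066 for mature oligodendrocyte genes. The same normexp versions ended the calls of Hedgehog and Wnt targets (adjusted p = 0.0737 and 0.0726) and mature oligodendrocyte genes (0.06 and 0.0726), and the latter call also ended with the authors' deposited values (0.0702) and without the filter on dim probes (0.0679).

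Cholesterol synthesis genes fell with a median of -0.18 over 23 members, 19 of them lower in both pairs, with the demethylase Cyp51 at -0.42 and squalene synthase Fdft1 at -0.36 (adjusted p = 0.000274; adjusted p = 0.441 with an estimated correlation). The mitosis list fell with a median of -0.14 over 29 members, 21 of them lower in both pairs, with the motor Kif11 at -0.43 and the checkpoint kinase Bub1b at -0.28 (adjusted p = 0.0048; adjusted p = 0.441 with an estimated correlation). DNA replication genes fell with a median of -0.15 over 31 members, 19 of them lower in both pairs, with the polymerase subunit Pola1 at -0.38 and Mcm3 at -0.31 (adjusted p = 0.0414; adjusted p = 0.723 with an estimated correlation). Without DMSO replicate 2 the adjusted p = 0.214 for cholesterol synthesis and 0.479 for mitosis, and the DNA replication list turned to higher (adjusted p = 0.0616). Without resveratrol replicate 1 the mitosis list had an adjusted p = 0.0521 and the DNA replication list again turned to higher (adjusted p = 0.57). Without the intensity trend the DNA replication call ended (adjusted p = 0.0509).

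**Figure D2:**
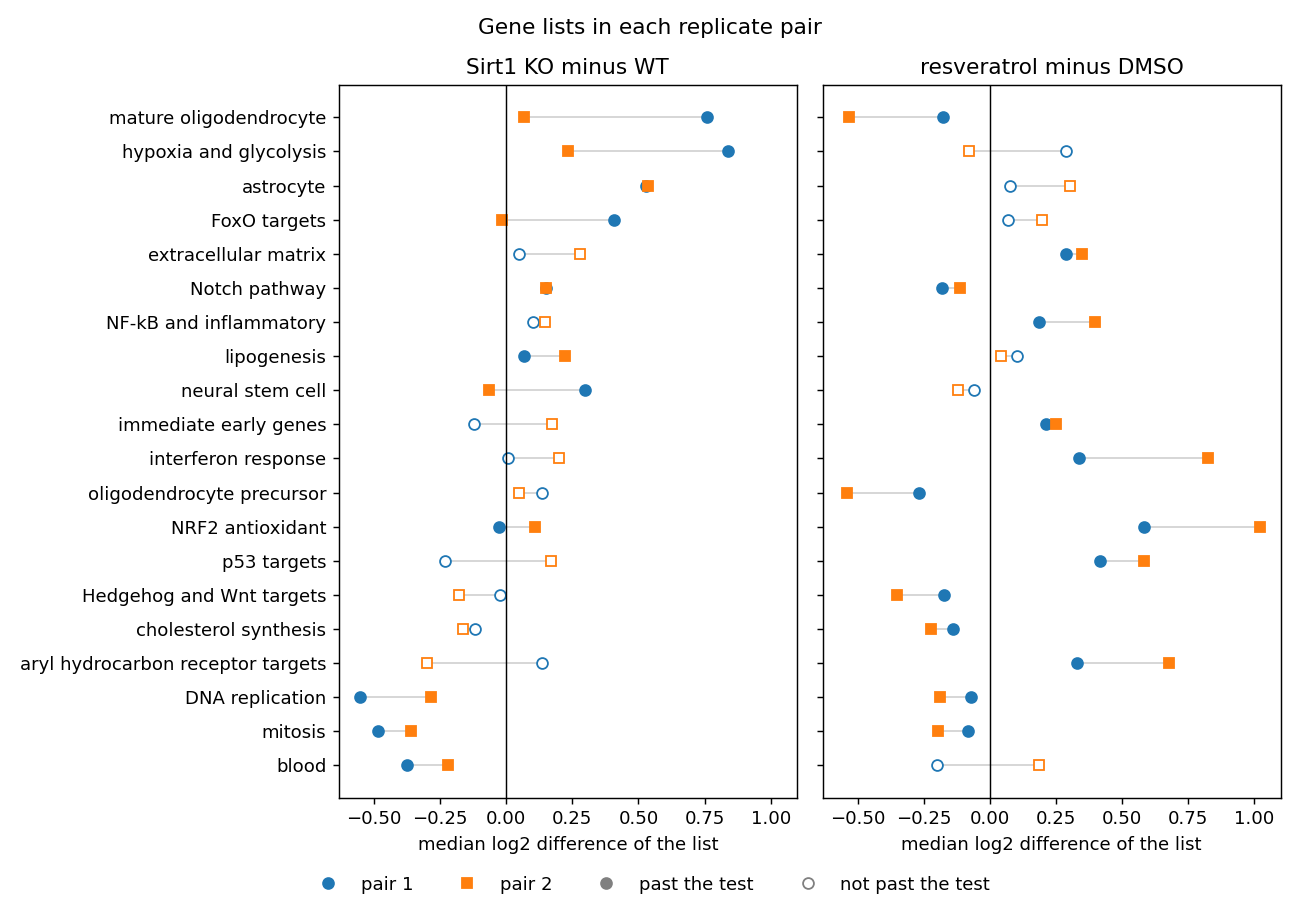
Median log2 difference of each gene list (horizontal axis) for the 20 lists past the test in at least 1 comparison (vertical axis), Sirt1 KO minus WT on the left and resveratrol minus DMSO on the right; circles are pair 1, squares pair 2, and filled symbols mark lists past the test with the preset correlation. NRF2 antioxidant genes had pair medians of 0.58 and 1.02 after resveratrol and -0.03 and 0.11 in Sirt1 KO, and mitosis genes had pair medians of -0.49 and -0.36 in Sirt1 KO.

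Higher after resveratrol were the glucuronosyltransferase Ugt1a6b (2.08, SE 0.37), the aldehyde oxidase Aox1 (2.31, SE 0.46) and the iron-binding protein Pir (1.80, SE 0.37). Others were Pqlc3 (1.47, SE 0.28), Erich3 (1.21, SE 0.24), Col18a1, Alox5, the copine Cpne7 (1.45, SE 0.33), the formin Inf2 (1.46, SE 0.35), Celf5 (1.06, SE 0.26), Cstad (1.03, SE 0.25) and the integrin Itga8 (1.33, SE 0.33). Lower after resveratrol were the ribonuclease angiogenin, Ang (-1.77, SE 0.51), the ammonium transporter Rhcg (-2.03, SE 0.59), the adhesion protein Lims2 (-1.16, SE 0.34), Fam89a (-1.22, SE 0.37), the anion transporter Slco2b1 (-1.20, SE 0.41), the kinase Prkcq (-1.20, SE 0.44) and Mfng. The olfactory receptor Olfr1510, the peptide receptor Grpr and the phosphatase Acpp were not well above background after resveratrol, and at least 4.17-fold, 1.89-fold and 1.55-fold lower. With 1 background per array Olfr1510 (-0.63), Grpr (-0.23) and Acpp (-0.05) differed by less than these bounds. The retroviral Erv3 was not well above background there either, and as its sign turned under both normexp versions (0.0074 and 0.033) no bound is given. With replicate number as a block, Hes5 (adjusted p = 0.0168), Ang (0.0259), Olfr1510 (0.0375) and Prkcq (0.0453) fell. The block also called the rises of Alox5 (0.0189), Erich3 (0.0246), Ugt1a6b, Aox1, Pir and Pqlc3 (0.0259 each), Col18a1 (0.0391) and Cpne7 (0.0413). Sirt1 mRNA differed by 0.10 (SE 0.24, adjusted p = 1), and its second probe by -0.10.

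limma called 0 of 13306 genes between resveratrol and DMSO in either direction (203 at an unadjusted p under 0.05, where chance gives 665; smallest adjusted p = 1). The replicate block gave 63 rises and 9 falls (1874 at an unadjusted p under 0.05), and 34 genes in all with quantile normalization. With slide as a block in the fit of all 8 arrays the count was 0 (607 at an unadjusted p under 0.05, smallest adjusted p = 0.877). Leaving out any 1 of the 8 arrays gave 0 genes. A difference of at least 2-fold upward was found in both pairs for 79 genes and downward for 18, and 7 genes differed by 2-fold in opposite directions. Pair 1 lies within slide 1 and pair 2 within slide 2, and their differences correlated at 0.506 across genes.

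Of the 32 lists, 7 rose and 7 fell after resveratrol, and 0 were past the test with an estimated correlation (smallest adjusted p = 0.131) or with fry. With either block 15 lists passed and all 14 were among them. Over all genes the replicate block called 9 of 25 NRF2 antioxidant genes, 3 p53 targets with 1 more lower, 1 extracellular matrix gene, 1 Notch gene, 1 mature oligodendrocyte gene and 0 members of the other lists that passed. Adjusted over the list alone it called 21 NRF2 antioxidant genes, 18 p53 targets with 1 more lower, 7 interferon response genes, 6 extracellular matrix genes with 1 more lower, 2 aryl hydrocarbon receptor targets, 3 NF-kB genes with 1 more lower and 6 immediate early genes. In the lists that fell, the block called 6 oligodendrocyte precursor, 6 mature oligodendrocyte and 6 Notch genes when adjusted over the list alone, 2 more mature oligodendrocyte genes as higher, and 0 genes of cholesterol synthesis, mitosis, DNA replication or Hedgehog and Wnt targets. Without a block the list alone gave only Hes5, in the Notch and neural stem cell lists. The crossed split of this arm passed 6 lists: oligodendrocyte precursor, mitosis, NRF2 antioxidant, cholesterol synthesis, integrated stress response, and hypoxia and glycolysis (smallest adjusted p = 3.91e-06).

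Hypoxia and glycolysis genes did not pass after resveratrol (adjusted p = 0.338), nor did neural stem cell (0.335), astrocyte (0.0938), neuronal lineage (0.573), microglia and macrophage (0.167), endothelial (0.128), pericyte with smooth muscle and fibroblast (0.464), ependyma with choroid plexus (0.218) or blood (0.827) genes. Sirtuins and NAD metabolism (0.332), PGC-1alpha and mitochondrial genes (0.317), FoxO targets (0.687), lipogenesis (0.338), the unfolded protein response (0.226) and BMP and TGF-beta targets (0.687) were not past the test. Sex-linked genes (0.254) and the chromosome 10 neighbours of Sirt1 (0.204) were not either. The integrated stress response list (adjusted p = 0.0845) was past the test, as lower, with replicate number as a block (adjusted p = 0.00374) and with slide as a block (adjusted p = 0.0307). Both blocks used the preset correlation, and without a block the estimated correlation gave an adjusted p = 0.614. For the neuronal lineage, blood, and BMP and TGF-beta lists, the median, the mean and the test differed in sign.

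The third comparison sets the effect of losing Sirt1 against that of resveratrol, to ask whether they differ. Hes5 stood out, higher in Sirt1 KO and lower after resveratrol, with a difference between the effects of 3.47 (SE 0.49 without a block, n = 2 arrays per group, adjusted p = 0.0048 with replicate number as a block). Further large positive differences past the blocked test were those of the oligodendrocyte precursor receptor Gpr17 (3.12, adjusted p = 0.0182), the tetraspanin Cd82 (3.08, adjusted p = 0.0182) and Mfng (2.66, adjusted p = 0.0489). The largest negative ones were Alox5 (-3.73, adjusted p = 0.0182), the protease inhibitor Cst6 (-3.19, adjusted p = 0.0167), Itga8 (-3.02, adjusted p = 0.0286), the chemokine Pf4 (-2.96, adjusted p = 0.0182) and cytidine deaminase Cda (-2.58, adjusted p = 0.036). Itga8 was lower in Sirt1 KO and higher after resveratrol, whereas Alox5 and Cst6 differed mainly through their rise after resveratrol. Without a block limma called 0 genes (126 at an unadjusted p under 0.05, where chance gives 665; smallest adjusted p = 1). The replicate block gave 45 (21 positive and 24 negative, with 1594 at an unadjusted p under 0.05), and 18 with quantile normalization. Slide as a block gave 0 (957 at an unadjusted p under 0.05). Without Sirt1 KO replicate 2 limma called 3, all negative.

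Some genes that the replicate block called in both comparisons were named after their values were seen. Hes5, the cell cycle inhibitor Cdkn1c (1.49 and -1.02) and the cell polarity cadherin Celsr1 (1.44 and -0.92) rose in Sirt1 KO and fell after resveratrol. The references of the comparisons are of different strains. Clic5 fell and then rose (-0.93 and 1.61), Me1 rose in both (0.95 and 0.86), and 0 genes fell in both. In WT, the reference of the first comparison, Hes5 read 2.78, and in DMSO, the reference of the second, 5.22.

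**Figure D3:**
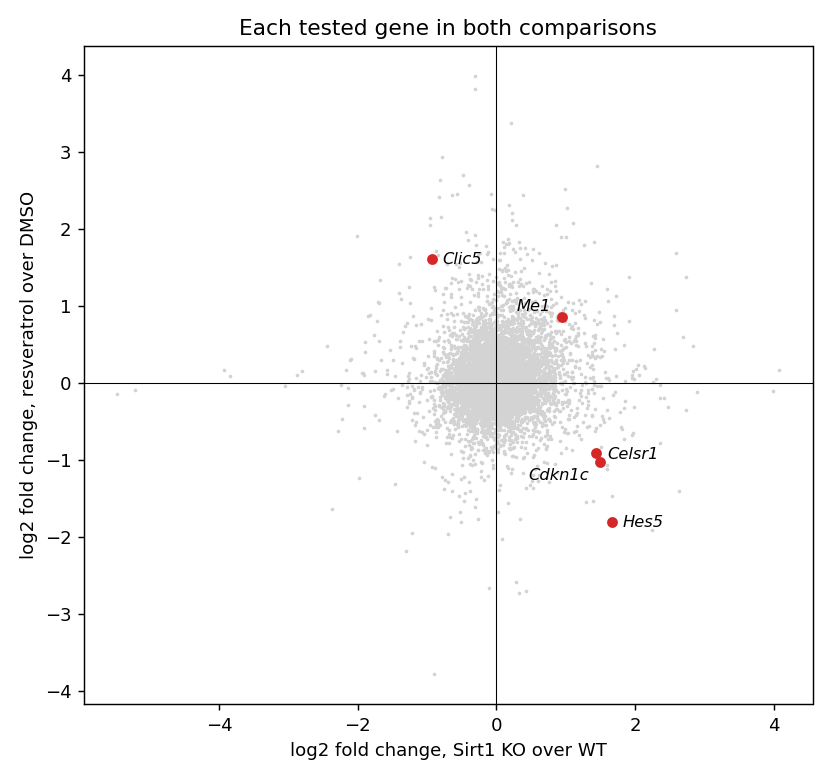
Log2 fold change of each of 13306 genes in Sirt1 KO over WT (horizontal axis) and resveratrol over DMSO (vertical axis), each from 2 arrays per group; red points are named genes called in both comparisons with replicate number as a block. Hes5, Cdkn1c and Celsr1 lie at the lower right, and the cloud as a whole has a Pearson correlation of 0.0664.

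Across all genes the log2 fold changes of the comparisons correlated weakly (Pearson 0.0664, Spearman 0.082, over 13306 genes that are not independent replicates). Other splits of the arrays within the arms gave Pearson values from -0.214 to 0.699, the highest where both arms were split by replicate number. Left-out arrays moved the value between -0.0886 and 0.216.

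The effects differed in 12 of 32 lists, of which 6 were higher and 6 lower in Sirt1 KO than after resveratrol. The Notch pathway (median difference 0.27, adjusted p = 2.88e-07; adjusted p = 0.216 with an estimated correlation) and NRF2 antioxidant genes (-0.69, adjusted p = 8.89e-08; adjusted p = 0.28 with an estimated correlation) stayed past the test without any of the 8 arrays. Oligodendrocyte precursor and mature oligodendrocyte genes differed by 0.47 and 0.54 (adjusted p = 2.06e-05 each; adjusted p = 0.132 each with an estimated correlation), and each had an adjusted p = 0.0516 without Sirt1 KO replicate 1. Targets of p53 (-0.62, adjusted p = 0.000353; adjusted p = 0.541 with an estimated correlation), interferon response (-0.53, adjusted p = 0.00212; adjusted p = 0.306) and aryl hydrocarbon receptor targets (-0.80, adjusted p = 0.00389; adjusted p = 0.219) were lower. Neural stem cell (0.16, adjusted p = 0.00173; adjusted p = 0.216 with an estimated correlation), astrocyte (0.34, adjusted p = 0.00427; adjusted p = 0.432) and hypoxia and glycolysis genes (0.42, adjusted p = 0.00212; adjusted p = 0.541) were higher. Mitosis (-0.29, adjusted p = 0.00269; adjusted p = 0.521 with an estimated correlation) and DNA replication genes (-0.26, adjusted p = 0.0391; adjusted p = 0.816) were lower in this difference. With replicate number as a block 13 lists passed, all 12 among them, and with slide as a block 8 did. The slide block ended the calls of neural stem cell, mitosis, interferon and aryl hydrocarbon receptor lists (adjusted p from 0.0837 to 0.0873). Normexp on median signals ended p53 (adjusted p = 0.562), astrocyte (0.155) and mature oligodendrocyte calls (0.782), and turned mitosis (0.432) and DNA replication (0.27) to higher. With 1 background per array only the DNA replication call ended (0.0577).

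Leaving out 1 array ended most of these calls. Without Sirt1 KO replicate 1 the adjusted p lay between 0.0516 and 0.0909 for neural stem cell, astrocyte, mitosis, p53 and interferon genes, and the DNA replication and hypoxia lists reversed (adjusted p = 0.81 and 0.535). Without WT replicate 1 it was 0.105 for neural stem cell and aryl hydrocarbon receptor genes, 0.132 for astrocyte and mitosis genes, and 0.0587 for DNA replication and interferon genes. Without WT replicate 2 it was 0.636 for DNA replication and 0.546 for hypoxia genes, and without Sirt1 KO replicate 2 it was 0.415 for aryl hydrocarbon receptor targets. Without DMSO replicate 1 it was 0.616 for astrocyte, 0.0609 for mitosis and 0.737 for hypoxia genes, and DNA replication reversed (adjusted p = 0.404). Without resveratrol replicate 2 it was 0.15 for astrocyte and 0.177 for p53 genes, and DNA replication and hypoxia genes reversed (adjusted p = 0.715 and 0.426). Mitosis had 0.163 without resveratrol replicate 1, and aryl hydrocarbon receptor targets had 0.0869 without that array and 0.0689 without DMSO replicate 2. Among the 20 lists not past the test, the median and the test differed in sign for PGC-1alpha and mitochondrial genes (median -0.09, higher by the test), and the median and the mean for pericyte genes (0.03 and -0.01). Adjusted over the list alone and without a block, 2 Notch genes and 1 neural stem cell gene passed, and 0 over all genes.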

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

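Normexp on median signals, normexp with 1 background per array, the replicate block with quantile normalization and the crossed split were chosen after seeing the data, and the other alternatives before. The count of genes in the fit of group means stayed at 0 in all 3 comparisons under each alternative without a replicate block in which all arrays of the comparison were kept. The replicate block gave 50 genes for Sirt1 KO against WT, 72 for resveratrol against DMSO and 45 for the difference between the effects, and with quantile normalization 24, 34 and 18. With 1 array left out, where the lone array of a group is assumed to vary like the others, counts ran from 0 to 5 for Sirt1 KO, stayed at 0 for resveratrol and ran from 0 to 3 for the difference. Arrays of the same replicate number shared deviations (correlations of 0.736 for WT with Sirt1 KO and 0.834 for DMSO with resveratrol). The replicate block removes this shared spread, and the fit of group means keeps it as noise. That fit gave 158, 203 and 126 genes at an unadjusted p under 0.05, where chance gives 665. Its counts of 0 thus do not show that no gene differed. The cause of the changes with left-out arrays was not tested.

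Some list calls ended with the estimated correlation although the estimate lay below the preset 0.01. Examples in Sirt1 KO are mature oligodendrocyte (estimate -0.00224, camera adjusted p = 0.209) and lipogenesis genes (-0.0224, 0.264). After resveratrol, oligodendrocyte precursor genes are another (0.00478, 0.131). A larger correlation between genes does not account for these losses. The number of gene lists past the test was 0 with an estimated correlation and 0 with fry in each comparison. With 1 array left out it ran from 5 to 13 for Sirt1 KO, from 7 to 14 for resveratrol and from 5 to 15 for the difference. Of 835 repeats of called lists, 638 kept direction and call, 184 kept only the direction and 13 reversed. Among them are repeats that left out an array of the other arm, which change the differences little. Normexp on median signals kept 4 of the 11 Sirt1 KO lists (astrocyte, blood, FoxO, and hypoxia and glycolysis), ended the calls of mitosis (adjusted p = 0.354), DNA replication (0.854), Notch (0.0701), neural stem cell (0.0698), NRF2 (0.0698) and lipogenesis genes (0.0754), and reversed mature oligodendrocyte genes there (adjusted p = 0.603), and mitosis (0.432) and DNA replication (0.27) in the difference. There it also ended p53 targets (0.562), astrocyte (0.155) and mature oligodendrocyte genes (0.782), and 1 background per array ended DNA replication (0.0577). After resveratrol both normexp versions ended 4 calls: mature oligodendrocyte (0.06 on median signals and 0.0726 with 1 background per array), NF-kB (0.184 and 0.208), immediate early genes (0.06 and 0.0591) and Hedgehog and Wnt targets (0.0737 and 0.0726). With 1 background per array the blood call in Sirt1 KO ended as well (0.428). DNA replication in the difference also ended without the filter on dim probes (0.0829). Blood, and aryl hydrocarbon receptor targets had too few members well above background on all arrays to be tested there. Left-out arrays reversed FoxO targets (adjusted p from 0.00181 to 0.915) and hypoxia and glycolysis (3.18e-11 to 0.846) in Sirt1 KO, and DNA replication (2.52e-08 to 0.57) and Hedgehog and Wnt targets (0.00311 to 0.615) after resveratrol. In the difference they reversed DNA replication (1.79e-06 to 0.81) and hypoxia and glycolysis (1.31e-07 to 0.737).

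Of 990 repeats of named genes other than Sirt1, 952 kept direction and side of the threshold, 32 passed it, each under a replicate block, and 6 reversed. None of these genes was past the threshold in the fit of group means, so keeping its side means staying not past it. The genes were also picked for a small p in these data, so the counts do not show that gene results are stable. Under normexp on median signals Sp8 read -0.45, Helt -0.70, Gfap -1.18 and Angptl4 -0.24 in Sirt1 KO against WT, and Erv3 0.0074 after resveratrol. That fit had a noise term of 179 on WT 1 and 57.1 on WT 2, against at most 2.69 on the other arrays, because 10 and 8 spots lay more than 100 below a very bright local background. It raised dim probes in WT only. With 1 background per array Erv3 was the only named gene reversed (0.033), while the list calls given above for that version were lost. Sirt1 read -0.15 in Sirt1 KO against WT with the mean of its probes, -0.087 with slide as a block and from -0.24 to 0.25 with 1 array left out. After resveratrol it read -0.00044 with the mean of its probes and from -0.010 to 0.21 with 1 array left out. The correlation of the effects was -0.227 with normexp on median signals, -0.0247 without a filter on dim probes, -0.104 with slide as a block and -0.0886 to 0.216 with 1 array left out.

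Background correction on mean signals was not run, no correlation was computed without the intensity trend or with only the 4 arrays, and the difference between the effects has no fit on 4 arrays. Signal over background limits genes such as Gfap and Helt, whose bounds hold only for the background-subtracted signals.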

Other observations

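The test of hypoxia and glycolysis genes across replicates was chosen only after that result was seen. WT and DMSO cells, the references of the comparisons, differ in strain and treatment. They also differ in sex for replicate 1 and in slide and scan day for replicate 2, so their difference has no single source. Its genes are named here after their values were seen. DMSO minus WT called 5 genes higher and 6 lower (746 at an unadjusted p under 0.05). The progranulin gene Grn read 8.69 in WT and 0.78 in DMSO (difference -7.91, SE 0.65, adjusted p = 0.0193), and likewise 8.75 in Sirt1 KO and 0.94 after resveratrol. The synaptotagmin Syt10 (-7.29), the chemokines Ccl19 (-5.08) and Ccl17 (-3.37), the integrin Itga9 (-3.81) and the potassium channel Kcnh2 (-2.64) were lower in DMSO as well. The fucosyltransferase Fut10 was higher (2.27). Rab26 and Klhdc9 (6.75 and 3.84) were higher too, with 1 of 2 WT arrays well above background, and Slx1b and Myo7a were not well above background in WT.

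Genes that differed between Sirt1 KO and WT were examined for linkage, since a knockout in a mixed background may carry blocks of linked strain variants. Among the 200 genes with the largest blocked statistic, 37 pairs lay within 10 tested genes of each other, against a mean of 29 (SD 5.32) and a 95th percentile of 38 in 10000 random draws. The count lay just below the bound, so linked haplotypes stay open. Genes described above were among these pairs. Dera, Mfng, Gfap, Serpinb1a and Itga8 lay beside genes that moved the same way. Sp8 and Rapgef5 neighbour each other and moved in opposite directions. Padi2, Alox12, Me1, Nusap1 and Pf4 each lay beside a gene that moved the other way, and Tpi1 had neighbours of both kinds. Loss of SIRT1 itself was not separated from linked haplotypes.

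Resveratrol differences were larger in pair 2 than in pair 1, with a ratio of median absolute differences of 1.8 (bootstrap interval over genes 1.76 to 1.85). Dim signal in pair 2 would need a ratio near 1 in the 3105 brightest genes, and it was 1.89 there (1.79 to 1.98). The scaling to the 75th percentile would need it near 1 with quantile normalization, and it was 1.62 (1.58 to 1.67). For these pairs the values argue against each as the whole source. The intervals resample genes, so they do not measure how the ratio would vary between arrays or cultures. Pair and slide coincide, and a difference in dose or response between cultures was not tested.

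Hypoxia and glycolysis genes were higher in the Sirt1 KO arrays by a median of 0.50, and lower in replicate 2 than in replicate 1 of each group, with median differences of -0.69 in WT, -1.51 in Sirt1 KO, -0.83 in DMSO and -1.43 in resveratrol. The smallest of these was 1.4 times the genotype difference, but they share a sign, so their common part cancels within replicate pairs and does not account for the rise. Replicate 2 arrays were also dimmer than replicate 1 arrays in each group, so culture and signal strength were not separated in the replicate differences. Within pairs the list was higher by 0.84 and 0.24, with 24 members higher and 0 lower in both pairs. With the preset correlation camera gave an adjusted p = 2.37e-18 with replicate number as a block and 2.65e-07 without. With an estimated correlation (0.297), run without a block only, camera gave an adjusted p = 0.442. A culture difference between the arrays of a pair may still contribute, and so may loss of SIRT1. What keeps both open is that each pair holds 1 array per genotype.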
